A study of Mus musculus with 24 samples.

How the data were processed

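RNA was measured in the nucleus accumbens of mice, a ventral striatal region built mainly of GABAergic medium spiny neurons. Per the labels, the tissue was punched on both sides, the RNA was isolated with TRIzol and chloroform, and libraries were made with an Illumina kit for stranded mRNA. The mice had undergone a sham operation or tibial spared nerve injury (SNI) of the left sciatic nerve, a model of lasting neuropathic pain. An adeno-associated virus (AAV8) with the neuronal hSyn promoter had been injected into the accumbens, carrying either Egfp alone or Mef2c with Egfp. The 24 libraries therefore form 4 groups of 6, named here Sham Gfp, Sham Mef2c, SNI Gfp and SNI Mef2c after surgery and vector. The design text names C57BL/6J or DBA/2J mice aged 8 to 9 weeks without saying which library came from which strain. Sex, batches and the mice behind each library are not given in the sources used here.

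The authors deposited a table of raw counts per gene and a table of FPKM. Per the labels, the counts came from featureCounts on the mm10 mouse genome, and the aligner, the annotation and the featureCounts version are not given in the sources used here. Both tables held 55401 gene IDs, of which 54349 matched a GENCODE M21 symbol with the ID version and 55141 without it, and 11852 IDs had no count in any library. Of the deposited FPKM values above 0, 100% equalled the count divided by the library total and by 1 length per gene, within a relative tolerance of 1e-06. That length equalled the gene span, introns included, for 42625 of the 42625 genes that could be compared. Among genes lying inside another gene, with at least 1000 counts over all libraries, the outer gene had at least as many counts in every library in 824 of 824 pairs on the same strand and in 1217 of 1217 pairs on opposite strands. Reads were therefore counted over the whole gene span without regard to strand, and a gene inside another shares its reads with it. For this reason genes whose span overlaps a gene with more counts are named as uncertain.

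Total counts per library lay between 25477019 and 36570108 over the 24 libraries. Among the 60 pairs of libraries within a group, the smallest chi-square per degree of freedom was 3.22 over genes with at least 20 counts in the pair, so no pair was a copy.

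Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, libraries were scaled by TMM, and a quasi-likelihood model with robust dispersions and 1 coefficient per group was fitted to all 24 libraries, leaving 20 residual degrees of freedom. The number of genes tested was 23738. P-values are two-sided and were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. The comparisons were SNI against sham with each vector, the Mef2c vector against the Gfp vector with each surgery, the interaction of surgery and vector, and the vector effect averaged over surgery. Levels are given as CPM, counts scaled by library size, with TMM scaling, fold changes as log2 values with their standard error (SE), and list means as log2 CPM with a prior count of 2. The level of Mef2c was also compared by exact permutation tests on log2 CPM.

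The comparisons, the model, 47 gene lists, the rule for naming genes and most of the other settings tried were fixed before the data were examined. The rule names Mef2a, Mef2b, Mef2c and Mef2d in every comparison. Among genes with an adjusted p under 0.05 and a mean of at least 1 CPM in a compared group, it names the 10 largest rises, the 10 largest falls and the 5 smallest p-values, and it counts but does not name predicted genes. Where fewer than 5 genes passed, it names the 10 smallest unadjusted p-values as values that did not pass. It adds up to 4 members of each list by smallest p, and a gene named in 1 comparison may be given in the others. It also names the members of the lists for the MEF2 family, the sex chromosomes and strain differences.

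Each list was tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, two-sided, with adjustment over the 47 lists. The alternatives were a correlation estimated per list and fry, whose test asks whether the genes of a list move on balance in 1 direction. Counts of list members past the threshold are given over all genes and adjusted over the list alone. For genes with no count in a whole group, the fold is a lower bound from a floor of 3 counts over that group. For genes with 1 to 3 counts the ratio has an exact 95% interval, and these intervals and floors cover counting error only.

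The other settings fixed beforehand were the median-of-ratios scaling of DESeq2 (RLE) or the library size alone, other filters on low counts (at least 1 CPM in 6 libraries, or any count), DESeq2 1.42.0, limma-voom with quality weights, and limma-trend on the deposited FPKM with 1 or 0.1 added before the log2. Further ones were the replicate number as a block, the compared groups alone, 2 surrogate variables from sva 3.50.0, Xist or the mean of cortical neuron markers as a covariate, and leaving out each library in turn. Chosen after seeing the data were the omission of the Sham Mef2c libraries 2 and 5, the restriction to genes that overlap no gene with more counts, and 1 further correlation between comparisons. The power of the model was tested on simulated counts with known changes, with each gene drawn independently. Each gene count was also compared with 60 random splits of the same libraries. The tables were read in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. No library was left out of the reported comparisons.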

Results

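Bulk mRNA was sequenced from the nucleus accumbens of mice that had a sham operation or spared nerve injury (SNI) and that had received a viral vector for Egfp (Gfp) or for Mef2c with Egfp (Mef2c). MEF2C is an activity-dependent transcription factor of neurons. Each of the 4 combinations of surgery and vector had 6 libraries. The total count per library lay between 28924194 and 34078177 in Sham Gfp, 28328510 and 33991197 in Sham Mef2c, 28101826 and 36570108 in SNI Gfp and 25477019 and 35601890 in SNI Mef2c. The labels do not say which mice gave which library, so p-values measure the spread between these libraries. In the labels the sequencing index runs by group, so an order of preparation, if it followed that index, coincides with the groups. The first principal component took 45.3% of the variance and the second 14.6%.

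The level of Mef2c itself was compared first, since the vector carries this gene (chromosome 13, 83504034 to 83667080, mm10). Mef2c stood at 169 CPM in Sham Gfp (SD 25.9, n = 6) and at 168 CPM in SNI Gfp (SD 39.2, n = 6). In SNI Mef2c it rose to 611 CPM (SD 146, n = 6), and 6 of 6 libraries lay above the highest SNI Gfp library at 221 CPM. The exact permutation test over 924 assignments gave a 3.64-fold rise after SNI (two-sided p = 0.00217). In the libraries labelled Sham Mef2c the level was 243 CPM (SD 128, n = 6), with single libraries between 123 and 469 CPM. Of these 6 libraries, 3 lay above the highest Sham Gfp library at 212 CPM, and libraries 2 and 5 lay below the Sham Gfp mean. The exact permutation test did not separate Sham Mef2c from Sham Gfp (1.30-fold, two-sided p = 0.264), and SNI Mef2c exceeded Sham Mef2c 2.74-fold (exact two-sided p = 0.00217). These tests did not adjust for tissue content. The mean of cortical neuron markers was 3.72 log2 CPM in Sham Gfp (SD 0.73) and 3.015 in Sham Mef2c (SD 0.626). Sham Mef2c libraries 2 and 5 had 2.719 and 2.556. In SNI Gfp, libraries 2 and 4 had the highest cortical means (3.503 and 5.155) and the highest Mef2c (221 and 213 CPM). Whether cortical tissue shifted the comparison of the sham groups was not tested.

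**Figure D1:**
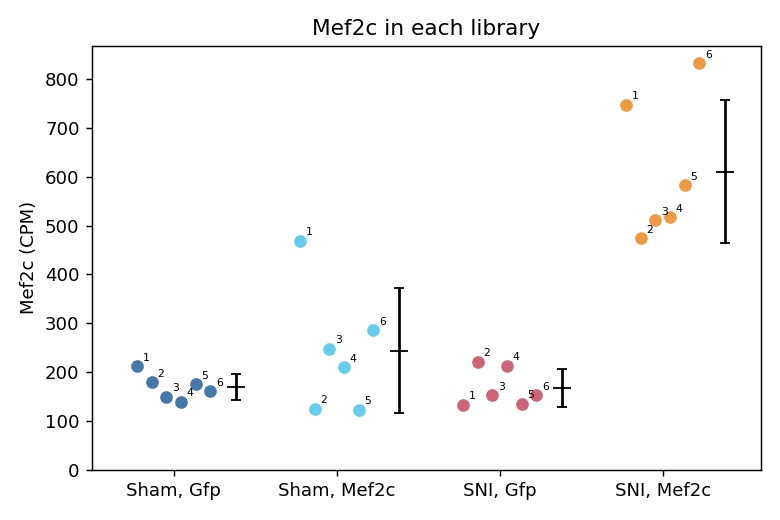
Level of Mef2c in CPM (y axis) in each numbered library of the 4 groups (x axis), with the group mean and bars of 1 SD (n = 6 per group). The 6 SNI Mef2c libraries lie between 474 and 832 CPM, and the Sham Mef2c libraries lie between 123 and 469 CPM.

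The other family members did not pass in any comparison. Mef2d had a mean of 276 CPM in Sham Gfp (SD 39.9), 286 CPM in Sham Mef2c (SD 33.1), 291 CPM in SNI Gfp (SD 26.0) and 329 CPM in SNI Mef2c (SD 6.03), with n = 6 in each. Mef2a, whose span overlaps the more abundant Lysmd4, lay between 121 CPM in Sham Mef2c and 135 CPM in SNI Mef2c. Mef2b lay between 14.0 CPM in SNI Mef2c and 15.3 CPM in Sham Mef2c. Of the 4 measured members of the MEF2 family list, 1 passed with the Mef2c vector after SNI over all genes and 1 adjusted over the list alone. That member was Mef2c, which the vector carries, so the list does not show a response of the family. The list had a median log2 fold change of 0.15 in that comparison (adjusted p = 0.314 with an estimated correlation).

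SNI was compared with sham in the Gfp libraries, which asks what nerve injury changes in the accumbens with the control vector. Genes of the interferon response, of antigen presentation and of microglia, the resident macrophages of the brain, had lower means after SNI, but no gene passed the threshold. Mx2, an interferon-induced antiviral GTPase (chromosome 16, 97535308 to 97560900), had 19.3 CPM in Sham Gfp (SD 6.96, n = 6) and 6.62 CPM in SNI Gfp (SD 4.34, n = 6), a log2 fold change of -1.53 (SE 0.31, adjusted p = 0.0929). Rsad2, an interferon-induced antiviral enzyme, had a log2 fold change of -1.54 (SE 0.35), and Ifit2, an interferon-induced RNA-binding protein, had -1.57 (SE 0.35), each with an adjusted p of 0.0929. The smallest adjusted p was 0.0517 for Sult6b1, a sulfotransferase (chromosome 17, 78883938 to 78906992), with 3.92 CPM in Sham Gfp (SD 0.849) and 2.38 CPM in SNI Gfp (SD 0.342).

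By list, 36 of 36 interferon genes passed as lower when adjusted over the list alone and 0 over all genes (median log2 fold change -1.68, adjusted p = 0.115 with an estimated correlation). Antigen presentation genes had 17 of 21 lower members adjusted over the list alone (median -1.36, adjusted p = 0.115 with an estimated correlation), among them Tapbp at -0.76 (SE 0.20) and the protease gene Ctss at -1.15 (SE 0.30). Microglia markers had 13 lower and 1 higher of 18 adjusted over the list alone (median -0.68, adjusted p = 0.115 with an estimated correlation), among them Tmem119 at -0.68 (SE 0.16) and the growth factor receptor gene Csf1r at -0.69 (SE 0.17). Cytokines and chemokines had 13 of 21 lower (median -0.61), reactive glia and complement genes 9 of 26 (median -0.93) and lymphocyte markers 2 of 23 (median -1.28), all adjusted over the list alone. Their adjusted p-values with an estimated correlation were 0.319, 0.347 and 0.319. The interferon mean was spread widely within SNI Gfp (2.86 log2 CPM, SD 1.66, n = 6), where library 6 had 5.30, library 4 had 4.49 and the lowest library had 1.37. With the preset correlation ribosomal protein genes were lower (7 of 54 adjusted over the list alone, median -0.14, adjusted p = 0.480 with an estimated correlation) and mitochondrially encoded genes higher (6 of 13, median 0.13, adjusted p = 0.480 with an estimated correlation). Pericyte and smooth muscle markers were called as higher with the preset correlation (median 0.84, 3 of 15 adjusted over the list alone, adjusted p = 0.510 with an estimated correlation). Their mean was 4.67 log2 CPM in SNI Gfp library 3 and at most 3.07 in the other 5 SNI Gfp libraries, against 2.61 in Sham Gfp (SD 0.15, n = 6), with Myh11, a smooth muscle myosin, at 6.99 CPM in Sham Gfp (SD 0.571) and 17.8 CPM in SNI Gfp (SD 21.9).

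With edgeR, 0 of 23738 genes passed between SNI and sham in the Gfp libraries, and 2928 had an unadjusted p under 0.05. DESeq2 called 553 genes (63 higher, 490 lower) and limma-voom with quality weights 2777 (952 higher, 1825 lower). The edgeR count depended on single libraries: it was 1392 without SNI Gfp library 6 and 880 without Sham Gfp library 3. It was 1 without each of Sham Gfp libraries 1 and 4, Sham Mef2c libraries 1, 3 and 6, SNI Gfp library 2 and SNI Mef2c libraries 4 and 5. With a preset correlation 19 of 47 lists were called, none with an estimated correlation, and 5 with fry (interferon, antigen presentation, microglia, lymphocyte and cytokine lists).

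The Mef2c vector was compared with the Gfp vector in sham mice, which asks what the vector changes without nerve injury. Genes of innate and adaptive immunity were far lower in the libraries labelled Sham Mef2c than in Sham Gfp. All 36 measured interferon genes fell (median log2 fold change -4.04), and the interferon list mean was 5.30 log2 CPM in Sham Gfp (SD 0.72, n = 6) and 1.45 in Sham Mef2c (SD 0.19, n = 6). The highest of the 6 Sham Mef2c libraries, at 1.72, lay below the lowest Sham Gfp library at 4.03. Irf7, a transcription factor that amplifies type I interferon (chromosome 7, 141262706 to 141266481), fell from 44.5 CPM (SD 24.4) to 1.54 CPM (SD 0.231), a log2 fold change of -4.85 (SE 0.65, adjusted p = 0.000161). Its span overlaps the more abundant Phrf1. Ifit1, an interferon-induced RNA-binding protein (chromosome 19, 34640871 to 34650009), fell from 42.6 CPM (SD 21.1) to 2.10 CPM (SD 0.802), a log2 fold change of -4.34 (SE 0.58). Isg15, a ubiquitin-like modifier, had a log2 fold change of -4.05 (SE 0.55) and Mx2 one of -2.73 (SE 0.32). The smallest adjusted p, 0.000139, was that of Sult6b1 with -1.05 (SE 0.12).

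All 21 antigen presentation genes fell in Sham Mef2c (median log2 fold change -4.59), which with the interferon list held with an estimated correlation (adjusted p = 0.0448 for interferon and 0.0451 for antigen presentation). B2m, the light chain of class I molecules (chromosome 2, 122147686 to 122153083), fell from 221 CPM (SD 54.2, n = 6) to 23.4 CPM (SD 4.05, n = 6), and its span overlaps Patl2. H2-D1, a class I heavy chain, fell from 614 CPM (SD 168) to 39.2 CPM (SD 8.59), a log2 fold change of -3.97 (SE 0.59), and H2-K1 had -4.22 (SE 0.64). Values of these 2 genes are uncertain, because related class I genes can share reads.

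Microglia markers were lower as a list (median log2 fold change -1.21, adjusted p = 0.0448 with an estimated correlation), with 14 of 18 falling and 1 rising, over all genes and adjusted over the list alone. Ctss, a lysosomal protease, fell from 332 CPM (SD 71.6, n = 6) to 73.0 CPM (SD 9.22, n = 6), and Tmem119, a membrane protein of microglia, from 38.6 CPM (SD 6.36) to 16.1 CPM (SD 1.84). P2ry12, a purine receptor of resting microglia, had 31.8 CPM in Sham Gfp (SD 2.35) and 29.5 CPM in Sham Mef2c (SD 1.36). The member that rose was Fcrls, a scavenger receptor of microglia (chromosome 3, 87250758 to 87263738), from 1.68 CPM (SD 0.432) to 3.98 CPM (SD 0.395), with a log2 fold change of 1.25 (SE 0.26, adjusted p = 0.00238). Reactive glia and complement genes had 21 of 26 lower over all genes and 22 adjusted over the list alone (median -1.86, adjusted p = 0.111 with an estimated correlation). C1qa, a chain of the first complement component (chromosome 4, 136895917 to 136898803), fell from 193 CPM (SD 58.4) to 35.8 CPM (SD 4.77). Gfap, the intermediate filament of astrocytes (chromosome 11, 102887336 to 102900912), fell from 369 CPM (SD 171) to 101 CPM (SD 25), a log2 fold change of -1.87 (SE 0.43, adjusted p = 0.00458). Cytokines and chemokines had 14 of 21 lower over all genes and 16 adjusted over the list alone (median -1.07, adjusted p = 0.111 with an estimated correlation), among them Ccl2, a monocyte attractant, at -5.37 (SE 0.83). The span of Ccl2 overlaps a predicted gene with more counts.

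Lymphocyte markers had 19 of 23 lower over all genes and 20 adjusted over the list alone in Sham Mef2c (median log2 fold change -3.88, adjusted p = 0.148 with an estimated correlation). The median stayed at -3.88 with the 2 members that had no count set to their bound. Cd8a, the co-receptor of cytotoxic T cells (chromosome 6, 71373427 to 71379173), had 956 counts over the Sham Gfp libraries and 0 over the Sham Mef2c libraries (4.95 CPM, SD 4.63, n = 6, against 0), at least 309-fold lower. Sham Gfp library 2 held 428 of the Cd8a counts, and without it the bound was 200-fold. Gzmb, a cytotoxic protease, had 1.46 CPM in Sham Gfp (SD 1.12) and was at least 91.2-fold lower, or at least 67.1-fold without the same library. Cd3e, a chain of the T cell receptor complex, had 478 counts against 3, a ratio of 154 (95% interval 52.4 to 750), or 116 without that library. Ccl5, a T cell chemokine, fell from 16.7 CPM (SD 12.3, n = 6) to 0.152 CPM (SD 0.181, n = 6). The blood cell list, by contrast, had a median of 0.25 with 0 of 4 members past the threshold.

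**Figure D2:**
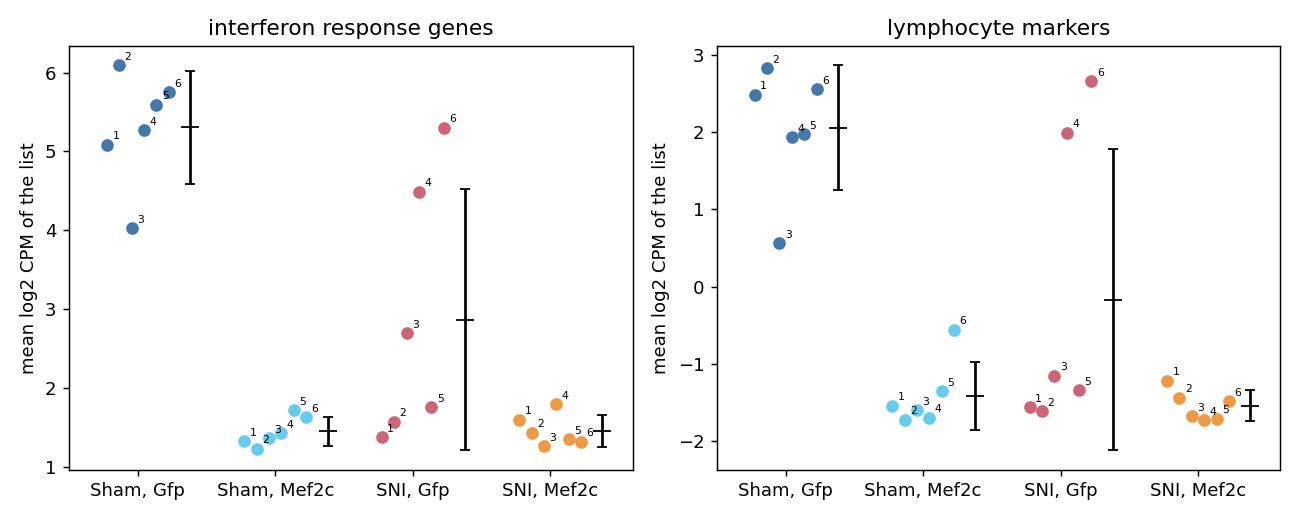
Mean log2 CPM of the interferon response list and of the lymphocyte marker list (y axes) in each library of the 4 groups (x axis), with group means and bars of 1 SD (n = 6 per group). The interferon means lie between 4.03 and 6.09 in Sham Gfp, between 1.37 and 5.30 in SNI Gfp, and at or below 1.79 in both Mef2c groups.

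Among markers of neighbouring regions, cortical neuron markers had a mean of 3.72 log2 CPM in Sham Gfp (SD 0.73, n = 6) and 3.02 in Sham Mef2c (SD 0.63, n = 6), and septal markers one of 3.96 (SD 0.34) and 4.51 (SD 0.49). The cortical list was not called (median log2 fold change -0.60, 0 of 17 members past the threshold), and the septal list was higher with the preset correlation (median 0.64, 0 of 8, adjusted p = 0.475 with an estimated correlation). Ribosomal protein genes had 18 of 54 lower over all genes and 36 adjusted over the list alone (median log2 fold change -0.16, adjusted p = 0.513 with an estimated correlation), such as Rps9 at -0.31 (SE 0.07) and Rplp0 at -0.34 (SE 0.08). Mitochondrially encoded genes had 5 of 13 higher over all genes and 9 adjusted over the list alone (median 0.21, adjusted p = 0.449 with an estimated correlation). Their largest rise was that of mt-Atp8, a subunit of ATP synthase, at 0.39 (SE 0.09), whose span overlaps mt-Atp6, while mt-Co2, mt-Co3 and mt-Nd4l did not pass without Sham Gfp library 5 or 6 or Sham Mef2c library 4. Without Sham Mef2c library 3 or 6 mt-Co2 and mt-Nd4l did not pass, nor did mt-Nd4l without Sham Gfp library 2, Sham Mef2c library 1, SNI Gfp library 2 or 5 or SNI Mef2c library 4 or 5. Synaptic adhesion and scaffold genes had 4 of 40 higher over all genes and 10 adjusted over the list alone (median 0.11, adjusted p = 0.395 with an estimated correlation), including Nlgn3, a postsynaptic adhesion molecule, at 0.13 (SE 0.04). Sham Mef2c library 6 stood apart in this list at 7.50 log2 CPM, and without it the Sham Mef2c mean was 7.06 instead of 7.13, against 6.99 in Sham Gfp. Of the 4 genes (Adgrl3, Nlgn3, Nrxn3 and Slitrk5), 4 did not pass without Sham Gfp library 5, 3 without Sham Gfp library 1 or 4 or Sham Mef2c library 6, 2 without Sham Gfp library 2 or 6 or Sham Mef2c library 2, 3 or 5, and 1 without Sham Mef2c library 1, SNI Gfp library 3 or SNI Mef2c library 2. GABA receptor genes had 1 of 21 higher over all genes and 5 adjusted over the list alone (median 0.21, adjusted p = 0.189 with an estimated correlation), the 1 being Gabbr1, a subunit of the GABA-B receptor, at 0.14 (SE 0.04). With scaling by library size alone neither Nlgn3 nor Gabbr1 passed (adjusted p = 0.116 for each), and Gabbr1 did not pass without Sham Gfp library 2, 5 or 6 or Sham Mef2c library 1, 2 or 3. The p53 and DNA damage list had 5 of 19 lower over all genes and 7 adjusted over the list alone (median -0.22, adjusted p = 0.395 with an estimated correlation), but Ccng1, Cdkn1a and Fas did not pass without Sham Gfp library 2 or 5. Without other single libraries of the 2 compared groups, except Sham Gfp libraries 3 and 4, 1 or 2 of these 3 genes did not pass. Carm1, an arginine methyltransferase and MEF2 coactivator, rose by 0.13 (SE 0.03, adjusted p = 0.00154). The list of neuronal MEF2 target genes had a median of -0.05 (adjusted p = 0.912), with 1 of 24 members lower over all genes and 0 adjusted over the list alone. That member was Cdkn1a, an inhibitor of the cell cycle, at -0.71 (SE 0.21, adjusted p = 0.0364), which did not pass with the replicate block, the cortical covariate, 2 surrogate variables, the compared groups alone, no count filter or the FPKM. It also did not pass without Sham Gfp library 1, 2, 5 or 6 or without Sham Mef2c library 2, 4 or 5.

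With edgeR, 2233 genes passed between Sham Mef2c and Sham Gfp, 351 higher and 1882 lower (84.3% lower). Of the lower genes 1069 changed more than 2-fold, against 9 of the higher genes. Limma-voom with quality weights called 4412 genes (1846 higher, 2566 lower), and leaving out Sham Gfp library 3 raised the count to 3602 (1323 higher, 2279 lower). With scaling by library size alone 132 genes were higher and 2069 lower. Of the 2233 genes, 373 were predicted genes and 471 overlapped a gene with more counts. Without the Sham Mef2c libraries 2 and 5, a choice made after seeing the data, 1670 genes passed (177 higher, 1493 lower). With a preset correlation 16 of 47 lists were called, against 3 with an estimated correlation.

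The Mef2c vector was compared with the Gfp vector after SNI, which asks what a raised Mef2c level changes in injured mice. Mef2c was the only gene that passed in edgeR, with a log2 fold change of 1.86 (SE 0.26, adjusted p = 0.00627). Cd74, the invariant chain of class II molecules, had 222 CPM in SNI Gfp (SD 337, n = 6) and 5.18 CPM in SNI Mef2c (SD 1.50, n = 6), and did not pass (adjusted p = 0.0891). H2-Aa, a class II chain whose reads related genes can share, had a log2 fold change of -5.84 (SE 1.22, adjusted p = 0.0891). Calcineurin subunit gene Ppp3cb had 0.19 (SE 0.06, adjusted p = 0.160) and Lgi1, a secreted synaptic protein, had 0.19 (SE 0.07, adjusted p = 0.199).

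After SNI, 36 of 36 interferon genes passed as lower with the Mef2c vector when adjusted over the list alone and 0 over all genes (median log2 fold change -2.13). Antigen presentation genes had 20 of 21 lower (median -2.98), lymphocyte markers 20 of 23 (median -4.10) and reactive glia and complement genes 18 of 26 (median -0.87), all adjusted over the list alone. Each of these 4 lists had an adjusted p of 0.314 with an estimated correlation. The interferon mean was 5.30 log2 CPM in SNI Gfp library 6, 4.49 in library 4 and 2.69 in library 3, while libraries 1, 2 and 5 (1.37, 1.57 and 1.76) lay within the SNI Mef2c range of 1.26 to 1.79. Mitochondrially encoded genes had 11 of 13 higher adjusted over the list alone (median 0.19, adjusted p = 0.314 with an estimated correlation). Medium spiny neuron markers had a median of 0.30 (0 of 24 members past the threshold, adjusted p = 0.419 with an estimated correlation), with a mean of 7.95 log2 CPM in SNI Mef2c and of 8.12 without library 1, and oligodendrocyte markers had one of -0.29 (0 of 19, adjusted p = 0.314 with an estimated correlation). Cortical neuron markers, which a punch of the accumbens can catch from neighbouring tissue, had a median of 0.46 (0 of 17, adjusted p = 0.374 with an estimated correlation). Their mean was 3.12 log2 CPM in SNI Gfp (SD 1.07), with library 4 highest at 5.155. In SNI Mef2c it was 3.87 (SD 1.13), with library 1 highest at 5.55. Neuronal MEF2 target genes had a median of 0.14 with 0 of 24 members past the threshold. Their list was called with the preset correlation (adjusted p = 0.0158), but had an adjusted p of 0.314 with an estimated correlation and of 0.202 with the cortical covariate.

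With edgeR 1 of 23738 genes passed between SNI Mef2c and SNI Gfp, and 3383 had an unadjusted p under 0.05. DESeq2 called 433 genes (35 higher, 398 lower) and limma-voom with quality weights 13 (2 higher, 11 lower). The edgeR count was 379 without SNI Gfp library 2, 162 without SNI Gfp library 5 and 153 without SNI Gfp library 1. Of 47 lists 28 were called with a preset correlation and none with an estimated correlation or fry.

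SNI was compared with sham in the Mef2c libraries, which asks what nerve injury changes with the Mef2c vector. No gene passed, Mef2c included (log2 fold change 1.33, SE 0.25, adjusted p = 0.223). Hspa5, the main chaperone of the endoplasmic reticulum, had 196 CPM in Sham Mef2c (SD 18.5, n = 6) and 159 CPM in SNI Mef2c (SD 12.9, n = 6). Lin7b, a scaffold protein of synapses, had a log2 fold change of 0.42 (SE 0.10), Mavs, an adaptor of antiviral signalling, -0.45 (SE 0.11) and Kcna1, a voltage-gated potassium channel, 0.48 (SE 0.14), each with an adjusted p of 0.223. Kcnj4, an inward rectifier potassium channel of medium spiny neurons, had 109 CPM in Sham Mef2c (SD 41.1) and 183 CPM in SNI Mef2c (SD 24, adjusted p = 0.223).

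Voltage-gated potassium channels were higher as a list in this comparison (8 higher and 2 lower of 39 adjusted over the list alone, 0 over all genes, median 0.23, adjusted p = 0.583 with an estimated correlation). Medium spiny neuron markers had a median log2 fold change of 0.40 (adjusted p = 0.626 with an estimated correlation) and cortical neuron markers one of 1.45 (adjusted p = 0.626 with an estimated correlation). Thalamic and hypothalamic markers had a median of -0.81 and septal markers one of -0.52 (adjusted p = 0.583 for each with an estimated correlation). The interferon list had a median of 0.02 between SNI Mef2c and Sham Mef2c and was not called. Neuronal MEF2 targets had a median of 0.15 (adjusted p = 0.626 with an estimated correlation, and 0.186 with the cortical covariate). With edgeR 0 genes passed and 3816 had an unadjusted p under 0.05, against 4 genes with DESeq2 (1 higher, 3 lower) and 0 with limma-voom. Without Sham Mef2c library 1 the edgeR count was 1, and 19 of 47 lists were called with a preset correlation against none with an estimated correlation.

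**Figure D3:**
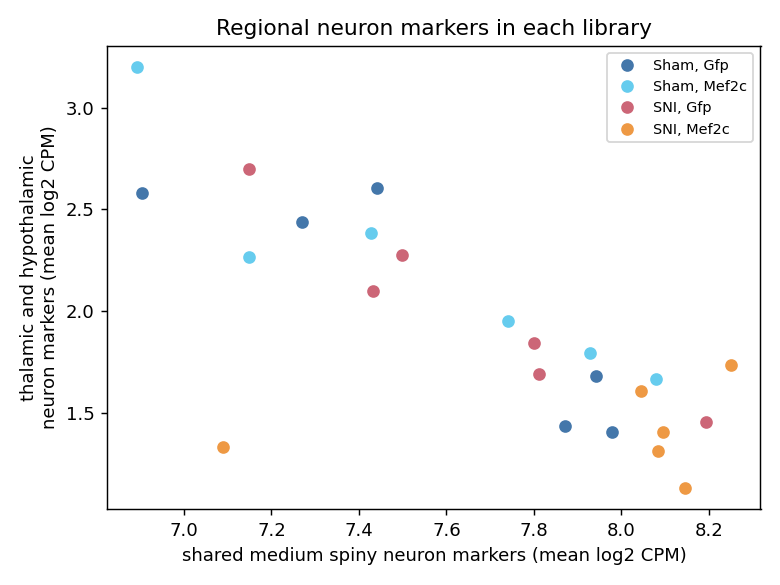
Mean log2 CPM of medium spiny neuron markers (x axis) and of thalamic and hypothalamic neuron markers (y axis), 1 point per library, coloured by group (n = 6 per group). The SNI Mef2c libraries lie at or below 1.73 on the y axis, and SNI Mef2c library 1 lies apart from its group on the x axis at 7.09.

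The interaction asks whether the effect of the vector differs between injured and sham mice. The interferon genes were lower with the Mef2c vector by less after SNI than after sham, with a median difference of 1.72 on the log2 scale and 19 of 36 members past the threshold adjusted over the list alone (0 over all genes, adjusted p = 0.567 with an estimated correlation). The interferon mean was 1.45 log2 CPM in Sham Mef2c and 1.46 in SNI Mef2c, against 5.30 in Sham Gfp and 2.86 in SNI Gfp. This difference thus restates the one between the 2 Gfp groups. Mx2 had a difference of 1.68 (SE 0.44, adjusted p = 0.313), Gpr84, a receptor of activated microglia, one of 1.43 (SE 0.35) and Sult6b1 one of 0.78 (SE 0.16). Mef2c had a difference of 1.34 (SE 0.35, adjusted p = 0.313). Microglia markers had 13 of 18 members past the threshold adjusted over the list alone (median 0.75, adjusted p = 0.567 with an estimated correlation). With edgeR 0 genes passed and 3529 had an unadjusted p under 0.05. DESeq2 called 1 gene and limma-voom with quality weights 4074 (1989 higher, 2085 lower), and without SNI Gfp library 6 edgeR called 269 (260 higher, 9 lower).

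Averaged over surgery, the Mef2c vector was compared with the Gfp vector over all 24 libraries. Mef2c rose by 1.19 on the log2 scale (SE 0.18, adjusted p = 7.3e-05) and interferon genes fell. The interferon fall did not part all Gfp libraries from the Mef2c libraries, whose list means reached 1.79 log2 CPM. SNI Gfp libraries 1, 2 and 5, without a Mef2c vector, had 1.37, 1.57 and 1.76. The highest means were those of Sham Gfp (4.03 to 6.09) and of SNI Gfp libraries 4 and 6 (4.49 and 5.30). Oasl2, an interferon-induced antiviral protein (chromosome 5, 114896936 to 114912234), had a log2 fold change of -4.05 (SE 0.48), Ifit1 one of -3.37 (SE 0.40) and Ddx60, an RNA helicase, one of -3.13 (SE 0.37), each with an adjusted p of 3.92e-05. All 36 interferon genes (median -3.06), all 21 antigen presentation genes (median -3.78) and 14 of 18 microglia markers (median -0.84) were lower, with 1 microglia marker higher, and these 3 lists held with an estimated correlation (adjusted p = 0.0391 for each). Lymphocyte markers had 21 of 23 lower (median -4.35, adjusted p = 0.124 with an estimated correlation). Mitochondrially encoded genes had 12 of 13 higher over all genes and 13 adjusted over the list alone (median 0.20, adjusted p = 0.211 with an estimated correlation). Among MEF2 partners and regulators 2 of 17 rose over all genes and adjusted over the list alone (adjusted p = 0.213 with an estimated correlation), Carm1 by 0.07 (SE 0.02) and Ppp3cb by 0.13 (SE 0.04). Neither passed without SNI Gfp library 6, and Ppp3cb did not pass without Sham Gfp library 2, 3, 5 or 6, Sham Mef2c library 1, 2, 3 or 6, SNI Gfp library 1, 3 or 5 or SNI Mef2c library 4, 5 or 6. Fcrls rose by 0.93 (SE 0.18), and Bves, a membrane protein of muscle and epithelium, rose by 0.43 (SE 0.11). With edgeR 2173 genes passed, 305 higher and 1868 lower, of which 852 were lower by more than 2-fold. The number of higher genes depended on the setting, with 74 for scaling by library size alone, 1038 with 2 surrogate variables and 742 without SNI Mef2c library 1. Of the 2233 genes called in sham mice, 1771 were also called in this average, which includes the same libraries, and 88.7% had the same direction after SNI, where none of them passed. Over all genes that share was 50.8%. The same 2233 genes went the same way in 99.8% of cases for SNI with the Gfp vector, against 79.3% over all genes. That comparison has no Mef2c vector, but it shares the Sham Gfp libraries, by whose difference these genes were called. Its high share is therefore set in part by that selection. It does not show whether the direction is particular to the Mef2c vector.

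Fold changes were correlated between comparisons across 23738 genes, which are not independent replicates, for 4 pairs of comparisons. The vector effect in sham mice and that after SNI share no library and had a Pearson r of 0.558 and a Spearman rho of 0.026, against an r of 0.007 in simulated groups without effect. Of all genes, 50.8% had the same sign in both. The simulated groups drew each gene independently and lack the differences that many genes share in these libraries. Their r therefore does not show how far r can lie from 0 without a vector effect. SNI with the Gfp vector and SNI with the Mef2c vector, which also share no library, had an r of -0.047 and a rho of -0.116 (simulated r -0.005). SNI with the Gfp vector and the vector effect after SNI share the SNI Gfp libraries and had an r of 0.484 and a rho of -0.052 (simulated r -0.496). With the shared libraries split, r was 0.785 and 0.043. The effect of SNI with the Gfp vector and the vector effect in sham mice share the Sham Gfp libraries, a pair chosen after seeing the data. Their r was 0.941 and rho 0.738, against a simulated r of 0.5, and r was 0.772 and 0.766 with the Sham Gfp libraries split.

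Markers of sex and strain were compared between the groups. Xist, transcribed from the inactive X chromosome, had a mean between 0.234 CPM in SNI Gfp and 0.287 CPM in SNI Mef2c, and the Y-linked Ddx3y one between 75.3 CPM in SNI Mef2c and 81.8 CPM in Sham Mef2c. No library had Xist above 0.421 CPM or Ddx3y below 67.3 CPM, so these genes showed no difference in sex between libraries. The sex chromosome list had 0 of 5 members past the threshold between Sham Mef2c and Sham Gfp (median log2 fold change 0.00). Nnt, a mitochondrial enzyme gene that is truncated in C57BL/6J mice, had a mean between 19.6 CPM in SNI Mef2c and 21.4 CPM in SNI Gfp. Single libraries had between 17.6 and 23.4 CPM of Nnt. Of the 5 strain genes, 1 fell in Sham Mef2c, Klrd1 (log2 fold change -4.87, SE 0.89, adjusted p = 0.000583), which is also a receptor of natural killer cells. Between Sham Gfp and Sham Mef2c, Gabra2 had 189 and 213 CPM, Glo1 52.4 and 56.2 CPM and Gpnmb 0.859 and 0.218 CPM.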

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

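All tests of explanations and all comparisons with random splits in this part were chosen only after the results were seen, whereas the interaction tests of the lists and the comparison of each library with its group were planned.

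Immune genes were lower in Sham Mef2c than in Sham Gfp, with 36 of 36 interferon genes and 21 of 21 antigen presentation genes called as lower. Blood left in the tissue would lower its own markers at least as much as those of microglia, but the 4 measured genes of the blood cell list had a median log2 fold change of 0.25 against -1.21 for microglia markers. For the lower genes as a whole, reads shared between overlapping genes are argued against by 1457 lower calls among genes that overlap no gene with more counts. Immune genes were not counted apart there, and the spans of Irf7, B2m and Ccl2 overlap other genes. A dependence on the Mef2c RNA level of the library is argued against as well: the Sham Mef2c libraries 2 and 5, with Mef2c below the Sham Gfp mean, had interferon means of at most 1.72 log2 CPM, below the lowest Sham Gfp library at 4.03. Some SNI Gfp libraries, which received no Mef2c vector, also had interferon means as low as 1.37 log2 CPM. Low means thus occurred without the Mef2c vector after SNI, but no Sham Gfp library lay below 4.03. The SNI Gfp libraries therefore do not decide on the source of the difference between the sham groups. A response to the vector preparation or the injection may have differed between the vectors, and this and an order of preparation stay open, while a biological effect of the vector that does not follow the measured Mef2c level was not tested.

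Mef2c was not raised in every library labelled Sham Mef2c, which ranged from 123 to 469 CPM. For a swap of labels with a Sham Gfp library, 0 of the 6 Sham Gfp libraries had an interferon mean at or below the highest Sham Mef2c library at 1.72 log2 CPM. The Sham Mef2c libraries 2 and 5 lay below the lowest Sham Gfp library at 4.03. This speaks to a swap only if the interferon mean marks the vector. SNI Gfp libraries had means as low as 1.37 without a Mef2c vector, so the test cannot decide on such a swap. A swap of labels with an SNI Gfp library cannot be told apart from correct labels, because 1 of the 6 SNI Gfp libraries, library 2, had both Mef2c (221 CPM) at or above the lowest other Sham Mef2c library at 210 CPM and an interferon mean (1.57) as low as theirs, but its Mef2c did not stand apart from SNI Gfp library 4 at 213 CPM. SNI Gfp libraries 2 and 4 also had the highest cortical neuron means of their group (3.503 and 5.155 log2 CPM, the others at most 2.539). Whether cortical tissue in the punch raised their Mef2c was not tested. A punch that missed part of the injected tissue could lower Mef2c together with medium spiny neuron markers: across the 6 libraries r was 0.618 (exact permutation p = 0.193), rho was 0.657 (exact p = 0.175), and r was 0.383 without the 2 farthest libraries. With 6 libraries this explanation cannot be told apart from no relation, and a failed injection, a single wrong label and a biological difference in vector expression between sham and injured mice were not tested.

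With a preset correlation, marker lists of neurons and glia were called between SNI Mef2c and SNI Gfp and between SNI Mef2c and Sham Mef2c, but with an estimated correlation no list was called (smallest adjusted p = 0.314 and 0.583). The place of the tissue punch is a candidate explanation: with group means removed, medium spiny neuron markers and thalamic and hypothalamic markers went in opposite directions across the 24 libraries (r = -0.747, permutation p = 5e-05, adjusted p = 1e-04 over 4 relations, rho = -0.809 with p = 1e-05, the smallest that 100000 permutations can give, and r = -0.669 without the 2 farthest libraries). The relation with oligodendrocyte markers had an r of -0.753 (permutation p = 1e-05, adjusted p = 4e-05), a rho of -0.631 (p = 0.00118) and an r of -0.663 without the 2 farthest libraries. For septal markers r was -0.384 (permutation p = 0.0639, adjusted p = 0.0852), rho -0.509 (p = 0.0122) and r without those libraries -0.721, and for cortical markers 0.219 (permutation p = 0.305, adjusted p = 0.305), 0.45 (p = 0.0284) and 0.576. A biological effect of injury and vector together on these cell types stays open and was not tested.

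The gene counts were compared with 60 random splits of the same libraries. Averaged over surgery, 1 of the 61 splits, the real one with 2173 genes, gave as many, and the highest other gave 1802. In sham mice 2 of 61 splits gave as many genes as the real 2233 and the highest other gave 2572, and after SNI 2 of 61 gave at least the real 1 gene and the highest other gave 414. Taken singly these 3 shares lie under 5%. No count could pass a correction over the 6 comparisons, since 1 of 61 is the smallest share that 60 random splits can give. The number of splits thus sets that outcome, and chance is not excluded. In the last 2 a random split gave more genes than the groups did, and the 1 gene after SNI was Mef2c, which the vector carries. For SNI with the Gfp vector, SNI with the Mef2c vector and the interaction the real count was 0, which 61 of 61 splits reach by definition, so the splits say nothing about chance there (highest other 4122, 0 and 1). For these 3 counts of 0 from edgeR, 2928, 3816 and 3529 genes had an unadjusted p under 0.05, DESeq2 called 553, 4 and 1 genes, and limma-voom called 2777, 0 and 4074. The splits with 4122, 2572, 414 and 1802 genes point to a structure of the samples. The first of them separated libraries with medium spiny neuron means of 7.80 or more from those of 7.50 or less, and the next 2 parted libraries by cortical markers, at 3.51 or more against 3.25 or less and at 2.75 or less against 3.5 or more. The split with 1802 genes put every library with an interferon mean above 4.03, among them Sham Gfp libraries 1, 2, 4, 5 and 6 and SNI Gfp libraries 4 and 6, on 1 side. With the cortical mean as a covariate, 2053 genes passed for the vector effect in sham mice (279 higher, 1774 lower).

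Libraries far from the other 5 of their group were found in 15 of 196 combinations of a group with a list mean, the total count or the Mef2c level, where chance gives about 1 in 20, or 9.8. SNI Mef2c library 1 stood apart in 9 list means. It was low for D1 markers (4.53 log2 CPM), D2 markers (5.33), shared medium spiny neuron markers (7.09), interneuron markers (3.32), GABA receptors (6.95), opioid, dopamine and cannabinoid genes (4.47) and cAMP signalling genes (7.67). It was high for muscle genes (1.44) and endothelial markers (4.86). SNI Gfp library 3 was high for pericyte and smooth muscle markers (4.67). SNI Gfp library 6 was high for choroid plexus markers (3.46) and low for oxidative phosphorylation genes (6.10). Sham Mef2c library 6 was high for lymphocyte markers (-0.56) and synaptic adhesion genes (7.50), and Sham Gfp library 4 was low for sex chromosome genes (4.37).

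The vector effect differed between injured and sham mice for 19 lists with a preset correlation and for none with an estimated correlation (smallest adjusted p = 0.567) or with fry (smallest adjusted p = 0.118). For the interferon list the means of the Mef2c groups were alike (1.45 log2 CPM in Sham Mef2c, 1.46 in SNI Mef2c), so its difference lay between the Gfp groups. The median log2 differences above 0 were 1.72 for interferon, 1.25 for antigen presentation, 1.24 for cortical markers, 1.00 for reactive glia, 0.98 for lymphocytes, 0.75 for microglia, 0.63 for cytokines, 0.44 for immediate early genes, 0.34 for medium spiny neuron markers, 0.19 for p53 genes and 0.10 for ribosomal proteins. Those below 0 were -1.10 for choroid plexus, -0.96 for thalamic and hypothalamic markers, -0.88 for septal markers, -0.42 for interneurons, -0.29 for oligodendrocytes, -0.27 for GABA receptors, -0.23 for oligodendrocyte precursors and -0.19 for cholesterol synthesis. The choroid plexus value rests in part on SNI Gfp library 6 at 3.46 log2 CPM, without which the SNI Gfp mean was 0.79 instead of 1.23.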

How the results depend on the processing

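The alternatives without the Sham Mef2c libraries 2 and 5, with only genes that overlap no gene with more counts, and the correlation of SNI with the vector effect in sham mice were chosen after seeing the data, and the others were planned. Except where named here, the total gene counts stayed within 1.5 times the reported count. No named gene that passed reversed its direction under any alternative. Of the values of genes named for the vector effect in sham mice, 381 of 7716 no longer passed and 146 newly passed, and for SNI with the Gfp vector 289 of 7445 newly passed. The causes of the differences below were not tested.

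For SNI with the Gfp vector (0 genes), 1 gene passed, Sult6b1, with RLE scaling, library size alone, at least 1 CPM in 6 libraries, the replicate block, and only genes overlapping no gene with more counts. There were 553 with DESeq2, 2777 with limma-voom, 731 with log2(FPKM + 1) (22 higher, 709 lower) and 770 with log2(FPKM + 0.1) (24 higher, 746 lower). For the vector effect in sham mice, limma-voom gave 4412. For the vector effect after SNI (1 gene), DESeq2 gave 433 and limma-voom 13. For SNI with the Mef2c vector (0 genes), DESeq2 gave 4 and log2(FPKM + 1) gave 1. For the interaction (0 genes), DESeq2 gave 1 and limma-voom 4074. The number of higher genes moved more than the total. In sham mice (351 higher) it was 132 with library size alone, 135 with no count filter, 130 and 117 with log2(FPKM + 1) and log2(FPKM + 0.1), 190 with the replicate block, 569 with DESeq2 and 1846 with limma-voom. Averaged over surgery (305 higher) it was 74, 113, 81, 83, 180, 500 and 765 in the same order, 179 with at least 1 CPM in 6 libraries, 528 with the cortical covariate and 1038 with 2 surrogate variables.

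Without the Sham Mef2c libraries 2 and 5, 1670 genes passed for the vector effect in sham mice (177 higher, 1493 lower). With all libraries kept, 1741 passed among genes overlapping no gene with more counts. The replicate block gave 1935 genes for the vector effect in sham mice (190 higher, 1745 lower). The replicate numbers did not pair the libraries: of 36 correlations between libraries of the same number 9 exceeded 0.1, with a range of -0.43 to 0.279.

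Leaving out each library in turn gave 0 to 1392 genes for SNI with the Gfp vector (1392 without SNI Gfp library 6, 880 without Sham Gfp library 3, and 1 gene without Sham Gfp library 1 or 4, Sham Mef2c library 1, 3 or 6, SNI Gfp library 2 or SNI Mef2c library 4 or 5) and 1731 to 3602 for the vector effect in sham mice (3602 without Sham Gfp library 3). It gave 1 to 379 for the vector effect after SNI (379, 162 and 153 without SNI Gfp libraries 2, 5 and 1), 0 to 1 for SNI with the Mef2c vector (1 without Sham Mef2c library 1), 0 to 269 for the interaction (269 without SNI Gfp library 6) and 1830 to 2851 for the average. The number of higher genes in sham mice was 1323, 132 and 213 without Sham Gfp libraries 3, 5 and 6, 224 without Sham Mef2c library 5 and 610 without SNI Mef2c library 1. Averaged, it was 174 and 166 without Sham Gfp libraries 5 and 6, 193 and 176 without Sham Mef2c libraries 1 and 3, 156 without SNI Gfp library 6, and 742 and 200 without SNI Mef2c libraries 1 and 4. The log2 fold change of Mef2c lay between 0.24 and 0.66 in sham mice and between 1.76 and 1.95 after SNI.

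With an estimated correlation 0 lists were called for SNI with the Gfp vector, 3 for the vector effect in sham mice, 0 after SNI, 0 for SNI with the Mef2c vector, 0 for the interaction and 3 for the average. With fry there were 5 for SNI with the Gfp vector, 12 for the vector effect in sham mice, 16 for the average and 0 for the vector effect after SNI, for SNI with the Mef2c vector and for the interaction. With the cortical covariate 18 lists were called for the vector effect after SNI and 12 for SNI with the Mef2c vector. The correlation of SNI with the Gfp vector and the vector effect in sham mice was 0.969 over genes with a mean of at least 10 CPM, against 0.941. In simulated counts at this depth, edgeR called 84% of 2-fold changes and 69% of 1.5-fold changes for the vector effect in sham mice, and 88% and 62% for SNI with the Gfp vector. Each simulated gene was drawn independently, without the immune and tissue differences that many genes share in these libraries. These shares therefore do not give the power to find such shared changes, and a count of 0 genes does not exclude them.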

Other observations

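The test of the Mef2c dose in this part was chosen only after the results were seen.

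Some marker transcripts varied widely between libraries of the same group. Ttr, the transthyretin of choroid plexus, had 3.20 CPM in Sham Gfp (SD 2.55, n = 6) and 136 CPM in SNI Gfp (SD 330, n = 6), where the highest library had 810 CPM and the lowest 0.103 CPM. Slc17a7, the vesicular glutamate transporter of cortical neurons, had 140 CPM in Sham Gfp (SD 128), 26.1 CPM in Sham Mef2c (SD 33.1), 107 CPM in SNI Gfp (SD 223) and 292 CPM in SNI Mef2c (SD 443). Igkc, the constant region of an antibody light chain made by B and plasma cells, had 134 CPM in Sham Gfp (SD 135), 19.4 CPM in Sham Mef2c (SD 45.8), 55.6 CPM in SNI Gfp (SD 98.5) and 0.428 CPM in SNI Mef2c (SD 0.596). Drd1, the dopamine receptor of direct-pathway medium spiny neurons, had 180 CPM in Sham Gfp (SD 54.2) and 226 CPM in SNI Mef2c (SD 83.4).

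The hypothesis that other genes follow the dose of Mef2c was tested by a regression on its level across the 12 Mef2c libraries, with surgery in the model. In edgeR 0 genes other than Mef2c passed among 22470 tested, the smallest adjusted p was 0.890, and 1147 had an unadjusted p under 0.05. With the cortical marker mean as a further term 0 passed, the smallest adjusted p was 0.998 and 592 had an unadjusted p under 0.05. With 12 libraries this leaves open whether other genes follow the dose of Mef2c.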
